A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

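Transcript levels were measured on 12 Affymetrix GeneChip arrays, each hybridised with labelled polyA RNA from 1 anaerobic chemostat culture of Saccharomyces cerevisiae CEN.PK113-7D, a haploid laboratory yeast of mating type a. A chemostat is a stirred vessel that is fed fresh medium and drained at the same rate, so that the growth rate is set by the dilution rate, here 0.03 per hour in every group. Growth was limited by carbon or by nitrogen at 12 °C or at 30 °C, which gives 4 groups of 3 arrays. Per the labels' protocols, the 3 arrays of a group came from separately grown cultures, so the spread within a group includes the spread between cultures. Groups and replicate numbers were taken from the sample titles.

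The deposited values are linear probe set intensities made with GCOS, the Affymetrix operating software, per the submitters' processing notes. The version, the signal algorithm and the scaling target are not given in the sources used here. In the deposited table the mean intensity after trimming 2% of the probe sets at each end was 150.1 on all 12 arrays, so the arrays had been scaled to a common level before deposit and total RNA per cell cannot be compared. No batch, scan date or hybridisation order is given in the sources used here. Probe sets were named through the platform annotation, with gene types from the R64 gene table. Of 9335 probe sets, 6504 had 1 gene, 328 had several and 2503 were not listed, and only those with 1 gene were tested. Among all probe sets, 60 were array controls.

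Signals below 12 were raised to 12 and log2 was taken, with no further scaling. Fold changes of genes near the floor are therefore understated. Where all 3 arrays of a group lay at or under the floor, the fold is a bound and is given as at least that size. Each gene was represented by its probe set with the highest mean log2 signal over all arrays. Of 5656 genes, 256 that exceeded the floor on fewer than 3 arrays were left out and 5400 were tested, 5259 of them protein-coding. For 303 genes with 2 or more probe sets this choice matters: their probe sets were called in opposite directions for 5 genes under carbon limitation and for 1 under nitrogen limitation. For 277 tested genes the probe set name carries a letter suffix, which can mark probes shared with other sequences. The kinds of suffix were not told apart. Such probe sets are pointed out where first named and are described below as sharing probes. Members of the HXT, PAU, TIR and ribosomal protein families are close in sequence, and a probe set of one member may read another.

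Means of the 4 groups were fitted with lmFit and compared with eBayes with an intensity trend, in limma 3.58.1 under R 4.3.3. All 12 arrays entered the fit so that the groups share an estimate of the spread. The contrasts were 12 °C against 30 °C under each limitation, the difference of these temperature effects (nitrogen minus carbon), and nitrogen against carbon limitation at each temperature. P values were adjusted by the Benjamini-Hochberg method over the 5400 genes of a contrast, all adjusted p values of genes below come from limma, and the threshold was 0.05. The number of arrays limits the precision: with 3 against 3, an exact two-sided permutation test cannot give a p below 0.1.

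For the text, named genes were the 10 largest rises and 10 largest falls per temperature contrast among genes past the threshold whose arrays did not overlap between the groups, the 10 each way with the largest smaller change in both limitations, the 8 each way with the largest difference of temperature effects, and the 8 and 5 each way that separated the limitations at 30 °C and 12 °C. Up to 4 members with the largest change were named per list, with the largest change against the list's direction. Genes known only by a systematic name were counted but not named.

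The 28 gene lists were cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerase I and III subunits, tRNA synthetases and translation factors, trehalose and glycogen metabolism, general stress genes, heat shock chaperones, Tir, Dan and Pau cell wall mannoproteins, other cell wall genes, fatty acid synthesis and desaturation, phospholipid synthesis, sterol synthesis and uptake, hexose transport and sensing, glycolysis with ethanol and glycerol formation, glucose-repressed and alternative carbon genes, nitrogen catabolite repressed genes, amino acid biosynthesis, sulfur assimilation and methionine, phosphate starvation genes, iron and zinc regulons, oxygen and heme responsive genes, the TCA cycle, the proteasome, autophagy and vacuolar proteases, cell cycle and histones, a-cell mating genes, alpha-cell and sporulation markers, and RNA degradation and helicases of cold adaptation. Each list was tested with camera, which compares a list's members with all other genes, at a preset inter-gene correlation of 0.01 and adjusted over the lists of a contrast. The calls were repeated with an estimated correlation and with fry, which asks only whether a list's genes move one way on balance. With an estimated correlation the calls of nitrogen catabolite repressed genes held for temperature under nitrogen limitation, for the difference of temperature effects and between limitations at 30 °C, and no other list call held.

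The groups, tests, gene lists, naming rule and most alternatives were set before the data were examined. The alternatives set then were other floors of 1 and 50, a pseudocount of 16, no filter or a mean signal of at least 50, quantile normalization, median scaling, other choices of probe set, no intensity trend, only the arrays compared, the replicate number as a block, a stricter threshold and leaving out each array in turn. An rRNA covariate and protein-coding genes only were added after the data were seen.

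The steps were tested on simulated data, drawn for the 5400 genes from their mean log2 signals and residual spreads with normal noise and with 200 changed genes per contrast. Of genes changed 2-fold and 4-fold, the fit recovered 73% and 96% for temperature under carbon limitation, 63% and 93% under nitrogen limitation, 62% and 88% between limitations at 30 °C, and 65% and 93% at 12 °C. For the difference of temperature effects it recovered 27% and 78%, and 9.48% of its calls were false, against 3.11% to 3.85% in the other contrasts. No unshifted list was called, but the noise was drawn gene by gene, so this does not test list calls among correlated genes. Each gene's noise also had the same spread on all arrays, while the real 12 °C arrays varied more than those at 30 °C. The rates therefore do not show how the fit performs on groups of unequal spread, such as the limitations at 12 °C.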

Results

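The data are 12 arrays of transcript levels in anaerobic chemostat cultures of the yeast Saccharomyces cerevisiae. There were 3 arrays each from carbon-limited and nitrogen-limited cultures at 12 °C and at 30 °C, all at a dilution rate of 0.03 per hour. Growth rate was therefore equal at both temperatures. The use of 2 limitations allows effects of temperature to be compared between nutrient regimes. Each array gave signals for 9335 probe sets, which were reduced to 5400 tested genes. The median signal per array lay between 41.2 and 51.4, and between 22.1% and 26.7% of probe sets lay under the floor of 12 signal units. The number of arrays limits the precision.

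Arrays of a group resembled each other, with correlations of log2 signals across genes between 0.952 and 0.986, where arrays of different groups reached 0.864 to 0.972 (genes are not independent replicates). At 12 °C the groups crossed: replicate 1 of carbon limitation correlated at 0.9722 with replicate 3 of nitrogen limitation. With its own replicates it reached 0.9698 and 0.9692. The median SD of a gene between replicate arrays was 0.26 and 0.28 on the log2 scale at 12 °C (carbon and nitrogen limitation) and 0.18 at 30 °C under both. The first 3 principal components held 44.5%, 23.8% and 8.80% of the variance, and replicate 1 of nitrogen limitation at 12 °C stood apart on the third of these.

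**Figure D1:**
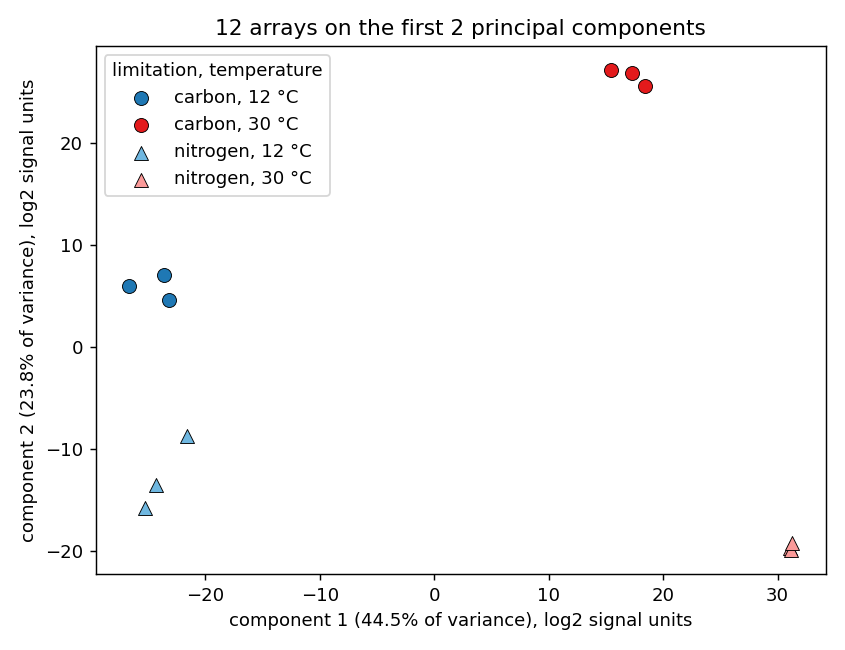
Principal components of log2 signals of 5400 genes, 1 point per array, coloured by group; the axes give component scores and the percent of variance held. The 3 arrays of each group lie together on the first 2 components, which hold 44.5% and 23.8% of the variance.

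Under carbon limitation, the amino acid permeases DIP5, BAP3, MUP1 and GNP1 and the stress proteins HSP30 and HSP26 were lower at 12 °C than at 30 °C, and the hexose transporter HXT4 was higher. Of 139 ribosome biogenesis genes 59 rose and 79 did not pass (adjusted p = 0.207 for the list with an estimated correlation). DIP5, a permease of acidic amino acids, fell from a signal of 1356 ± 40.0 (SD, n = 3) to 11.03 ± 3.0, a 107-fold change, with 2 of 3 arrays at 12 °C at the floor. HXT4 rose 32.5-fold, from 30.5 ± 1.82 to 1022 ± 290 (SD, n = 3). HSP26, a small heat shock chaperone, fell 20.9-fold, from 1124 ± 77.8 to 54.5 ± 11.2. In all, 1386 of 5400 genes changed, 707 upward and 679 downward. Of these, 552 changed by at least 2-fold, 227 upward and 325 downward. Signals of the 3 arrays at each temperature did not overlap for 42.7% of genes, against the 10% that chance gives.

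Among the other large rises, HPF1, a cell wall mannoprotein, rose 19.8-fold (log2 4.31 ± 0.27 SE, adjusted p = 1.43e-08), and EFM6, a methyltransferase of translation elongation factor 1A, rose 18.6-fold (adjusted p = 1.44e-08). PDR12, an exporter of weak organic acids, rose 12.7-fold, from 88.4 ± 21.1 to 1124 ± 305 (SD, n = 3). ARE2, a sterol acyltransferase, lay at the floor on all 3 arrays at 30 °C and rose at least 7.84-fold. PRM3, needed for nuclear fusion in mating, rose 7.22-fold and the small nucleolar RNA SNR50 rose 6.5-fold. The B-type cyclin CLB1, the glucose signalling gene STD1 and the cell cycle corepressor NRM1 rose 6.07-fold, 5.96-fold and 4.65-fold.

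Among the falls, RGI2, a gene of respiratory growth, went from 1377 ± 182 to 29.3 ± 5.6 (SD, n = 3), a 47.3-fold change. HXT5, a hexose transporter, lay at the floor on all 3 arrays at 12 °C and fell at least 39.8-fold from 484.6 ± 104. HSP30, a heat shock protein of the plasma membrane, fell 38.4-fold (log2 -5.26 ± 0.35 SE, adjusted p = 3.14e-08). The branched-chain amino acid permease BAP3 fell 26.3-fold and the methionine permease MUP1 16.3-fold, with 2 of 3 arrays at the floor at 12 °C for each. The hydrophilin gene GRE1 (1 array at the floor), the glutamine permease GNP1 and the cytochrome c oxidase subunit COX26 fell 17.6-fold, 14.4-fold and 13.8-fold.

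Ribosome biogenesis factors rose as a list (camera adjusted p = 4.51e-11, adjusted p = 0.207 with an estimated correlation). Of 139 measured members 59 rose, 1 fell and 79 did not pass, and adjusted over the list alone 69 rose and 2 fell. ALB1, KRR1 and MAK16 rose by 1.62, 1.33 and 1.30 on the log2 scale, and ESF1, with a change of -0.98, was the exception. Of 30 subunits and initiation factors of RNA polymerases I and III, 11 rose and 19 did not pass, among them RRN7 at 1.29 and RPA34 at 1.27 (15 rose when adjusted over the list alone; camera adjusted p = 0.000111, adjusted p = 0.207 with an estimated correlation). Of 81 measured cytosolic ribosomal protein genes 15 rose, none fell and 66 did not pass, with 11 rising when adjusted over the list alone (camera adjusted p = 1.36e-05, adjusted p = 0.448 with an estimated correlation). RPL7B rose by 2.07 and RPS22B by 1.36 (the probe sets of both share probes with other sequences), and the list's median was 0.28.

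General stress genes fell as a list: 30 of 57 fell, 6 rose and 21 did not pass (33 and 7 adjusted over the list alone; camera adjusted p = 1.86e-09, adjusted p = 0.207 with an estimated correlation). Besides HSP30, HSP26 and GRE1, SIP18 fell by 3.75, and GRE2 rose by 1.28. Of 32 heat shock chaperones 13 fell, 4 rose and 15 did not pass (14 and 4 adjusted over the list alone; camera adjusted p = 0.0112, adjusted p = 0.207 with an estimated correlation). AHA1, a cochaperone of Hsp90, fell by 1.68 and APJ1 by 1.52, and KAR2, the chaperone of the endoplasmic reticulum, rose by 0.71. Of 35 glucose-repressed and alternative carbon genes 20 fell, 2 rose and 13 did not pass (21 and 2 adjusted over the list alone; camera adjusted p = 1.21e-08, adjusted p = 0.207 with an estimated correlation). PCK1, the first enzyme of gluconeogenesis, fell by 3.13 and REG2 fell by 1.99, and SIP4 rose by 0.91. Of 36 oxygen and heme responsive genes 17 fell and 19 did not pass (20 adjusted over the list alone; camera adjusted p = 3.48e-06, adjusted p = 0.207 with an estimated correlation). QCR10, SDH1 and QCR2, subunits of respiratory complexes, fell by 1.58, 1.2 and 1.17.

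Spike-in controls read 519 ± 68.8 at 12 °C and 317 ± 33.4 at 30 °C under carbon limitation (SD, n = 3), and the ratio of 3' to 5' signal of ACT1 was 1.53 ± 0.379 and 1.82 ± 0.108. That of another control, TBP, went the other way, with 3.55 ± 0.539 at 12 °C and 2.94 ± 0.378 at 30 °C. Without replicate 1 at 30 °C, 921 genes changed in place of 1386. The calls of APJ1, RRN7 and SIP4 were lost with a floor of 50, that of ESF1 also with no filter on dim genes or without replicate 1 or 2 at 12 °C or 1 or 3 at 30 °C. GRE2 lost its call with that floor and without replicate 3 at 12 °C or 1 at 30 °C.

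Under nitrogen limitation, 35 of 46 nitrogen catabolite repressed genes fell at 12 °C (adjusted p = 0.0062 for the list with an estimated correlation), and 89 of 139 ribosome biogenesis genes rose (adjusted p = 0.0607 for the list with an estimated correlation). DIP5 fell 152-fold, from 1894 ± 104 to 11.5 ± 1.65 (SD, n = 3; 2 of 3 arrays at the floor at 12 °C). The general amino acid permease GAP1 fell 15.2-fold, from 3504 ± 391 to 229.7 ± 2.37. NSR1, a nucleolar protein of ribosomal RNA processing, rose 11.2-fold, from 73.7 ± 1.39 to 838.5 ± 200. In all, 2063 genes changed, 857 upward and 1206 downward, and 812 changed by at least 2-fold, 288 upward and 524 downward. Arrays did not overlap for 48.9% of genes, against 10% by chance.

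EFM6 rose 24.3-fold (log2 4.60 ± 0.26 SE, adjusted p = 3.94e-09), and PDR12 19.5-fold, from 73.5 ± 4.0 to 1442 ± 193 (SD, n = 3). The small nucleolar RNAs SNR67 and SNR72 rose 18.3-fold and 8.52-fold, and SNR50, at the floor on all 3 arrays at 30 °C, rose at least 19.7-fold. PRM3 rose 12.1-fold, FIG1, a membrane protein of mating cells, 9.55-fold, and MF(ALPHA)1, which encodes the alpha-factor pheromone, 9.12-fold. PIR3, a cell wall protein, rose 7.79-fold.

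The peptide transporter PTR2 fell 34.2-fold, the oligopeptide transporter OPT2 33.8-fold (1663 ± 149 to 50.1 ± 12.6, SD, n = 3) and the proline oxidase PUT1 29.2-fold. The flocculin gene FLO11 fell from 2060 ± 145 to 73.6 ± 9.05, a 28.1-fold change, and DAL5, the allantoate permease, from 2642 ± 143 to 101.3 ± 13.0, a 26.2-fold change. The hexose transporter HXT2 fell 20.5-fold (log2 -4.35 ± 0.23 SE, adjusted p = 1.27e-09), ISF1 18-fold and COX26 17.2-fold (1 array at the floor at 12 °C).

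Of 46 nitrogen catabolite repressed genes, which yeast shuts off when good nitrogen sources are plentiful, 35 fell, 2 rose and 9 did not pass, and adjusted over the list alone 36 fell and 2 rose. This list's call held in both forms of the test (camera adjusted p = 5.93e-15, adjusted p = 0.0062 with an estimated correlation). ASP1, with a rise of 1.08, was the largest exception. Of 139 ribosome biogenesis genes 89 rose, 1 fell and 49 did not pass (97 and 1 adjusted over the list alone; camera adjusted p = 1.3e-24, adjusted p = 0.0607 with an estimated correlation), with NOG2 at 2.45 and DBP3 at 2.14 after NSR1, and BUD23 at -0.70. Of 81 cytosolic ribosomal protein genes 56 rose and 25 did not pass (61 adjusted over the list alone; camera adjusted p = 1.61e-18, adjusted p = 0.16 with an estimated correlation), with RPL7B at 2.04 and RPL9A, whose probe set also shares probes, at 1.78. Of 30 RNA polymerase I and III genes 14 rose and 16 did not pass (18 adjusted over the list alone; camera adjusted p = 1.03e-06, adjusted p = 0.0607 with an estimated correlation), with RPA49 at 1.91 and RPA12 at 1.25. Of 55 tRNA synthetases and translation factors 21 rose, 2 fell and 32 did not pass (21 and 2 adjusted over the list alone; camera adjusted p = 1.99e-06, adjusted p = 0.0607 with an estimated correlation), with TEF4 at 1.41 and SUI1 at 1.2.

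Of 64 amino acid biosynthesis genes 21 rose, 3 fell and 40 did not pass (21 and 3 adjusted over the list alone; camera adjusted p = 0.000871, adjusted p = 0.16 with an estimated correlation). LEU9 rose by 2.14 and the lysine synthesis genes LYS9 and LYS1 by 1.88 and 1.81, and ARG1 fell by 1.08. Of 20 a-cell mating genes 9 rose and 11 did not pass (9 adjusted over the list alone; camera adjusted p = 0.000491, adjusted p = 0.16 with an estimated correlation), among them ASG7 at 2.56 and FIG2 at 2.25. Of 20 trehalose and glycogen genes 13 fell and 7 did not pass, with PIG2 at -2.11 and TSL1 at -1.96 (15 fell and 1 rose adjusted over the list alone; camera adjusted p = 6.43e-05, adjusted p = 0.256 with an estimated correlation). Of 57 general stress genes 27 fell and 30 did not pass, with TMA10 at -3.29, ROQ1 at -3.21 and HSP30 at -2.98 (29 fell and 1 rose adjusted over the list alone; camera adjusted p = 6.43e-05, adjusted p = 0.256 with an estimated correlation). Of 17 phosphate starvation genes 9 fell and 8 did not pass, with the phosphate transporters PHO84 at -3.32 and PHO89 at -2.16 (10 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.000246, adjusted p = 0.16 with an estimated correlation). Of 42 autophagy and vacuolar protease genes 20 fell and 22 did not pass, with the autophagy receptors ATG39 at -2.29 and ATG32 at -1.79 (22 adjusted over the list alone; camera adjusted p = 6.43e-05, adjusted p = 0.16 with an estimated correlation).

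Weaker list calls were those of heat shock chaperones, hexose transport and glucose-repressed genes. Of 32 heat shock chaperones 15 fell, 3 rose and 14 did not pass, with BTN2 at -2.21 (15 and 3 adjusted over the list alone; camera adjusted p = 0.0461, adjusted p = 0.256 with an estimated correlation). Of 20 hexose transport and sensing genes 10 fell, 2 rose and 8 did not pass, with HXT2 at -4.35, HXT5 at -3.48 and HXK2 at 0.96 (10 and 2 adjusted over the list alone; camera adjusted p = 0.0461, adjusted p = 0.352 with an estimated correlation). Of 35 glucose-repressed genes 13 fell, 3 rose and 19 did not pass, with MLS1 at -3.22, GUT2 at -2.02 and FBP1 at 1.49 (13 and 3 adjusted over the list alone; camera adjusted p = 0.0327, adjusted p = 0.352 with an estimated correlation). These list calls were lost in 6, 8 and 3 of the 19 alternatives run. The call of FBP1 was lost with a floor of 50. That of BUD23 was lost with median scaling and without replicate 2 at 12 °C or 2 or 3 at 30 °C. The median change of all genes was -0.10, and quantile normalization and median scaling moved it by 0.12 and 0.13. With these, 1073 genes rose and 931 fell, or 1132 rose and 922 fell, in place of 857 and 1206. The list tests set members against all other genes. Spike-in controls read 531 ± 205 and 522 ± 46.4 and the 3' to 5' ratio of ACT1 was 1.55 ± 0.223 and 1.82 ± 0.112 at 12 °C and 30 °C (SD, n = 3). That of TBP was 2.53 ± 0.539 at 12 °C and 3.13 ± 0.107 at 30 °C.

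The other 13 lists were called for temperature under neither limitation. For iron and zinc regulons (30 genes, camera adjusted p = 0.0643 under carbon limitation), 15 genes fell and 6 rose under carbon limitation and 15 fell and 4 rose under nitrogen limitation (15 and 8, and 15 and 5, adjusted over the list alone), with FIT2 at -3.35 under carbon and SIT1 at -2.04 under nitrogen limitation, both of iron uptake. Of 42 other cell wall genes 9 rose and 3 fell under carbon and 8 rose and 8 fell under nitrogen limitation, with the same numbers adjusted over the list alone, and CWP1 rose by 1.55 and 1.76. Of 19 fatty acid genes 6 rose and 6 fell, and 5 and 5, with MGA2, an activator of the desaturase gene, at -1.24 and -1.81 (7 and 6, and 5 and 6, adjusted over the list alone). Of 27 phospholipid synthesis genes 6 rose and 1 fell, and 5 and 4, the same adjusted over the list alone, with CHO1 at 1.38 and 1.57 and INO1 at 2.00 under carbon limitation. Of 32 sterol genes 6 rose and 3 fell, and 6 and 7, the same adjusted over the list alone, with ARE2 upward and the regulator SUT1 at -3.02 and -1.65. Of 28 genes of glycolysis and of ethanol and glycerol formation 5 rose and 3 fell, and 4 and 3 (6 and 3, and 4 and 2, adjusted over the list alone), with PDC6 at -2.14 and -2.79. Of 24 sulfur and methionine genes 9 rose and 5 fell, and 7 and 4 (12 and 5, and 7 and 4, adjusted over the list alone), with the sulfate permease SUL1 at -1.50 and -3.05.

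Of 21 TCA cycle genes 1 rose and 5 fell under carbon and 5 rose and 1 fell under nitrogen limitation (1 and 6, and 5 and 1, adjusted over the list alone), with DIC1 at 1.10 and 1.35. Of 37 proteasome genes 3 rose and 1 fell, and 0 and 2 (0 and 1 both times adjusted over the list alone), and the one that fell in both was the regulator RPN4 at -0.96 and -1.45. Of 36 cell cycle and histone genes 6 rose and 2 fell, and 4 and 8, the same adjusted over the list alone, with CLB1 at 2.60 and 1.65. Of 17 measured Tir, Dan and Pau genes 3 rose and 3 fell, and 1 and 5 (5 and 3, and 1 and 4, adjusted over the list alone), with TIR2 at 1.64 and 0.47 and DAN4 at -0.77 and -2.77. Of 15 alpha-cell and sporulation markers 2 rose and 2 fell, and 5 and 2, the same adjusted over the list alone, with MF(ALPHA)1 at 2.20 and 3.19 and IME1, the initiator of meiosis, at -1.55 and -1.22. Of 25 RNA degradation and helicase genes 4 rose and 1 fell, and 5 and 4, the same adjusted over the list alone, with DBP2 at 2.00 and 2.62. Median and mean differed in sign under carbon limitation for the proteasome (median -0.03, mean 0.04), nitrogen catabolite repressed genes (0.05 and -0.29) and phosphate starvation genes (0.13 and -0.26). Under nitrogen limitation they did so for sterol genes (0.08 and -0.06), sulfur and methionine genes (0.16 and -0.05), the proteasome (0.0031 and -0.03) and RNA degradation genes (-0.10 and 0.13). For fatty acid and phospholipid genes under nitrogen limitation both were negative and the camera direction was upward, without a call. Scaling turned the sign of the medians of sterol, glycolysis and RNA degradation genes under nitrogen limitation and of the proteasome under carbon limitation. With a floor of 50 the calls of PDC6 under carbon limitation, SUT1 under nitrogen limitation and IME1 under both were lost. DAN4 lost its call under carbon limitation without replicate 2 at 12 °C. TIR2 lost its call under nitrogen limitation with quantile normalization and without replicate 1 at 12 °C or 3 at 30 °C.

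**Figure D2:**
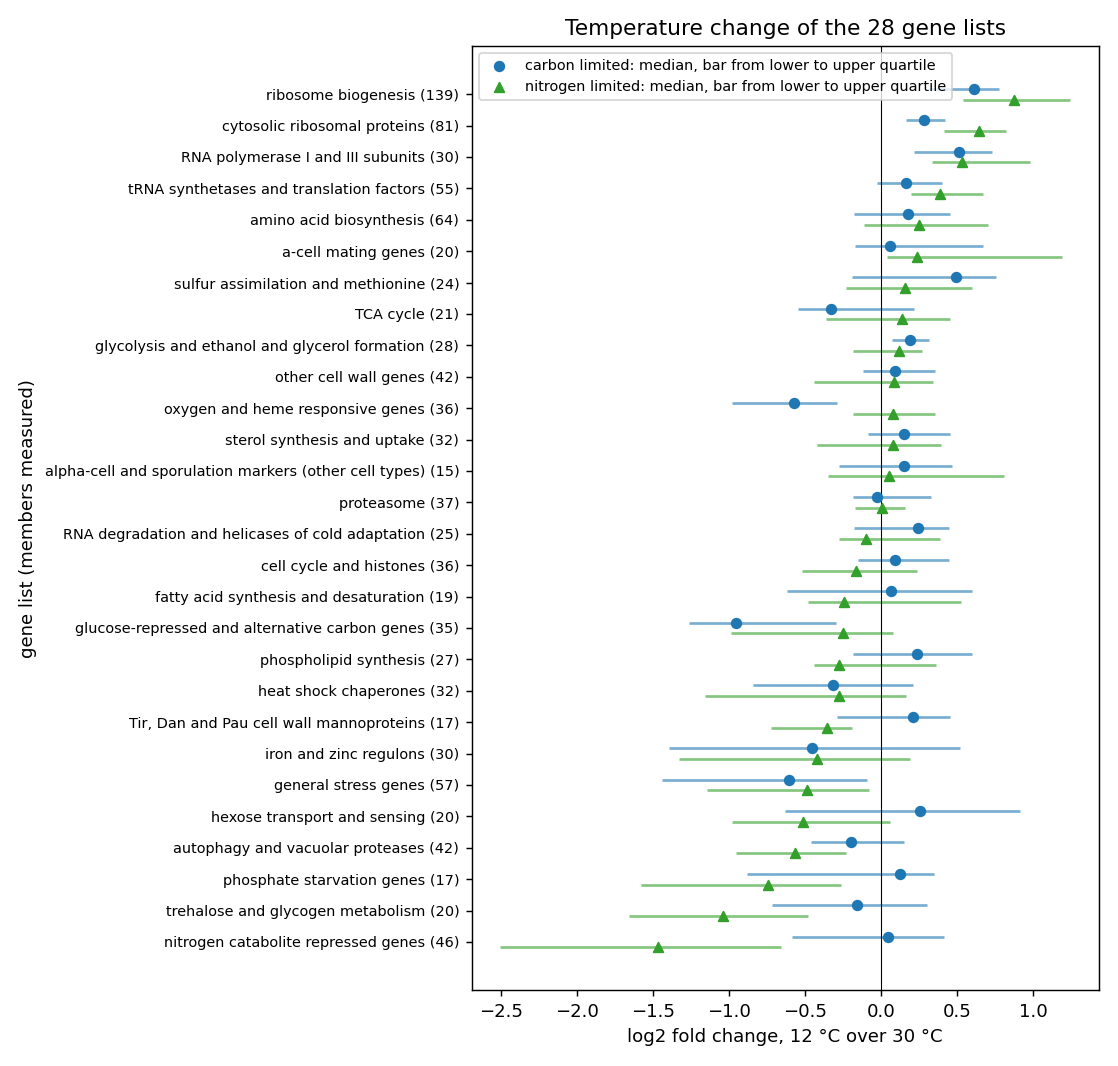
Median log2 change of each gene list between 12 °C and 30 °C under each limitation, with a bar from the lower to the upper quartile of its members. Nitrogen catabolite repressed genes have a median of -1.47 under nitrogen limitation and 0.05 under carbon limitation.

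Under both limitations, DIP5, COX26 and several stress genes were lower and EFM6, PDR12, PRM3 and SNR50 higher at 12 °C. The temperature contrasts share no array, and 815 genes changed in the same direction in both, 381 upward and 434 downward, where independent lists would give 112.2 and 151.6. The contrasts do share one estimate of each gene's spread. Genes of low spread can thus pass in both more often, and these independent counts may be too low. With quantile normalization 469 rose and 378 fell, and with median scaling 441 and 378, so the excess of falls turned. By at least 2-fold in both, 99 genes rose and 168 fell, and 35 genes changed in opposite directions. Across genes the log2 changes correlated with Pearson's r = 0.626 and Spearman's rho = 0.605, and 71.1% of genes had the same sign.

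The shared rises included HPF1 (19.8-fold and 4.16-fold), the RNA helicase DBP2 (4.01-fold and 6.14-fold), ASG7, a gene of a-type cells (3.96-fold and 5.91-fold), and MF(ALPHA)1 (4.58-fold and 9.12-fold). ARE2 rose at least 7.84-fold and at least 4.44-fold, its 30 °C arrays all lying at the floor, and the latter call was lost with a floor of 50. RPL7B rose 4.21-fold and 4.11-fold. The shared falls included PTR2 (12.2-fold and 34.2-fold), SPG4, a gene of stationary phase (11.3-fold and 13.0-fold), ISF1 (8.86-fold and 18-fold), HSP26 (20.9-fold and 6.97-fold), HSP30 (38.4-fold and 7.87-fold), ROQ1 (7.50-fold and 9.25-fold) and HXT5 (at least 39.8-fold, and 11.1-fold). SUF6, a tRNA gene whose probe set shares probes with other sequences, fell 8.07-fold and 6.99-fold, with 1 array at the floor at 12 °C under each limitation.

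**Figure D3:**
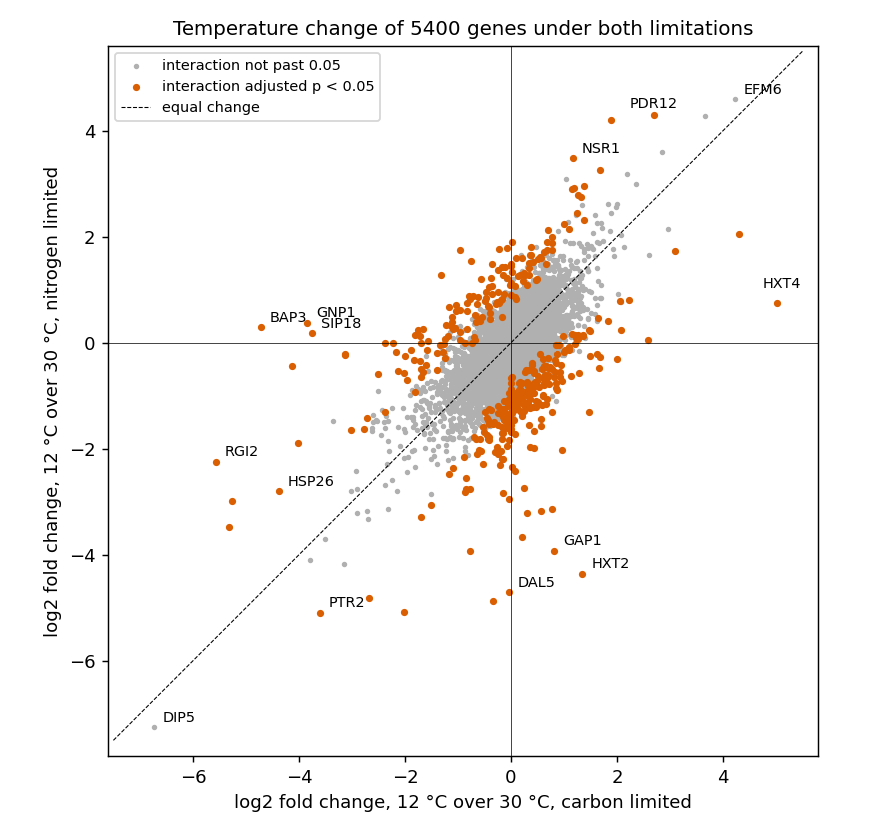
Log2 change between 12 °C and 30 °C of 5400 genes under carbon limitation (x axis) and nitrogen limitation (y axis), 1 point per gene, with the 402 genes whose changes differ in orange and a dashed line for equal change. Pearson's r across genes is 0.626.

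The temperature effect itself depended on the limitation for the hexose transporters HXT2 and HXT4, the nitrogen genes GAP1, DAL5 and PUT1 and the permeases BAP3 and GNP1. HXT2 rose 2.55-fold at 12 °C under carbon limitation (214 ± 28.6 to 557.3 ± 160, SD, n = 3) and fell 20.5-fold under nitrogen limitation (696.1 ± 24.3 to 35.0 ± 10.4), a log2 difference of -5.70 ± 0.32 (SE). GAP1 rose 1.76-fold under carbon and fell 15.2-fold under nitrogen limitation. GNP1 fell 14.4-fold under carbon limitation, and under nitrogen limitation was low at both temperatures (16.4 ± 3.29 at 30 °C and 21.5 ± 5.55 at 12 °C). In all, 402 genes differed, 157 with a more positive change under nitrogen limitation and 245 with a more negative one, and 348 differed by at least 2-fold, 132 and 216.

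Of the 402 genes, 211 passed the temperature test under nitrogen limitation alone, 89 under carbon limitation alone, 62 under both in the same direction, 35 under both in opposite directions and 5 under neither. The latter, singled out after their values were seen, were AIM2, CTP1, HIR3, PSK1 and SPC110. The change was larger under nitrogen limitation for 272 of them. DAL5, PUT1 and the repressor gene DAL80 had differences of -4.67, -4.52 and -3.86 on the log2 scale, the urea transporter DUR3 and the vacuolar carboxypeptidase CPS1 of -3.92 and -3.74, and HXT4 of -4.27 (adjusted p = 7.44e-08). In the other direction BAP3 differed by at least 32.4-fold (log2 5.02 ± 0.34 SE, adjusted p = 9.64e-08), with all 3 arrays of nitrogen limitation at 30 °C at the floor. SIP18, GRE1, SHH3 and PCK1, with differences of 3.93, 3.71, 2.92 and 2.90, fell under carbon limitation and had adjusted p values of 0.647, 0.104, 0.447 and 0.442 under nitrogen limitation. RGI2 had a difference of 3.32, an upper bound since it lay at the floor in nitrogen-limited cultures at 12 °C. A fall hidden by the floor could account for this difference. CYC1, cytochrome c, fell by 0.96 under carbon and rose by 1.75 under nitrogen limitation, a difference of 2.71. With a floor of 50 this difference and the rise lost their calls.

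Lists with a more negative change under nitrogen limitation were led by nitrogen catabolite repressed genes, of which 23 of 46 were lower and none higher (31 and 2 adjusted over the list alone; camera adjusted p = 1.33e-18, adjusted p = 0.00257 with an estimated correlation). Of 20 trehalose and glycogen genes 5 were lower, with TSL1 at -2.33 and the glycogen synthase GSY1 at -2.10 (8 adjusted over the list alone; camera adjusted p = 4.2e-05, adjusted p = 0.211 with an estimated correlation). Of 17 phosphate starvation genes 6 were lower, with SPL2 at -1.86, lost with a floor of 50 (8 adjusted over the list alone; camera adjusted p = 0.000131, adjusted p = 0.208 with an estimated correlation). Of 17 Tir, Dan and Pau genes 3 were lower, with DAN4 at -1.99 and TIR2 at -1.17 (4 adjusted over the list alone; camera adjusted p = 0.000426, adjusted p = 0.243 with an estimated correlation). Of 20 hexose transport genes 5 were lower and 2 higher, with STD1 at -2.53 and HXT5 at 1.84 or more, since its carbon-limited arrays at 12 °C lay at the floor (9 and 2 adjusted over the list alone; camera adjusted p = 0.000447, adjusted p = 0.208 with an estimated correlation). Of 42 autophagy genes 6 were lower, with ATG39 at -1.77 (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00559, adjusted p = 0.211 with an estimated correlation).

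Lists with a more positive change were oxygen and heme responsive genes, of which 9 of 36 were higher and 1 lower, with QCR2 at 1.85 and COX4 at 1.63 (14 and 1 adjusted over the list alone; camera adjusted p = 5.18e-09, adjusted p = 0.208 with an estimated correlation). Ribosome biogenesis genes followed, of which 15 of 139 were higher, with NSR1 at 2.32 and RCL1 at 1.88 (21 higher and 2 lower adjusted over the list alone; camera adjusted p = 1.08e-08, adjusted p = 0.211 with an estimated correlation). Of 81 ribosomal protein genes 2 were higher, RPL9A at 1.99 and RPL36B, whose probe set shares probes as well, at 0.78 (2 adjusted over the list alone; camera adjusted p = 4.59e-09, adjusted p = 0.243 with an estimated correlation). The latter call was lost without replicate 2 at 30 °C of either limitation. Of 35 glucose-repressed genes 6 were higher and 2 lower, with PCK1 at 2.90 and MLS1 at -3.51 (10 and 3 adjusted over the list alone; camera adjusted p = 0.000245, adjusted p = 0.208 with an estimated correlation). Of 64 amino acid biosynthesis genes 4 were higher, with SER1 at 1.48 (4 adjusted over the list alone; camera adjusted p = 0.0294, adjusted p = 0.243 with an estimated correlation, lost in 5 of 24 alternatives). Of 20 a-cell mating genes only FIG1 was higher, by 1.57 (1 adjusted over the list alone; camera adjusted p = 0.00297, adjusted p = 0.208 with an estimated correlation). Of 21 TCA cycle genes 3 were higher (3 adjusted over the list alone; camera adjusted p = 0.00429, adjusted p = 0.217 with an estimated correlation). Among 55 tRNA synthetases and translation factors none was higher and 1 was lower, and none passed adjusted over the list alone, while the list's median was 0.30 (camera adjusted p = 0.000111, adjusted p = 0.208 with an estimated correlation).

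Median scaling moved the median difference of all genes, -0.10, by 0.14, and 238 genes were then higher and 178 lower (227 and 220 after quantile normalization) in place of 157 and 245. Leaving out a 30 °C array lowered the count to 246 and 249 without carbon limitation replicates 1 and 2, and to 261 and 248 without nitrogen limitation replicates 1 and 2.

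**Figure D4:**
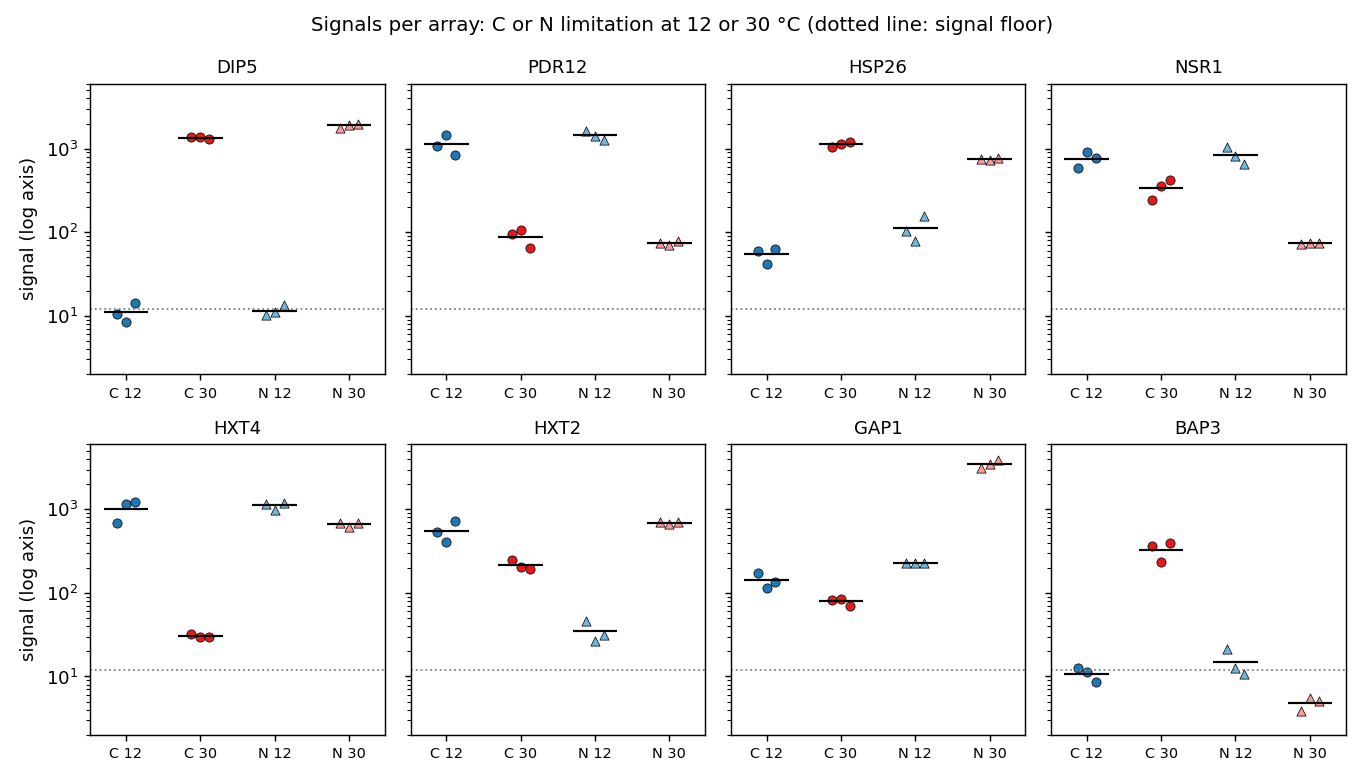
Signal of 8 named genes on each of 12 arrays, by group, on a log axis; horizontal lines are group means and the dotted line is the floor of 12 signal units. GAP1 has a mean of 3504 in nitrogen-limited cultures at 30 °C and of 79.2 in carbon-limited ones.

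At 30 °C, 30 of 46 nitrogen catabolite repressed genes were higher in nitrogen-limited than in carbon-limited cultures (adjusted p = 0.00241 for the list with an estimated correlation). GAP1 was 44.2-fold higher (79.2 ± 8.05 to 3504 ± 391, SD, n = 3) and DAL5 29.3-fold higher (91.0 ± 16 to 2642 ± 143). GNP1 was 29.9-fold lower, at 16.4 ± 3.29 against 489.9 ± 82.0, and BAP3 at least 26.7-fold lower, with all 3 nitrogen-limited arrays at the floor. In all, 1452 genes differed, 771 higher and 681 lower, and 542 by at least 2-fold, 288 higher and 254 lower. Scaling turned the balance, with 648 higher and 793 lower after median scaling and 765 and 838 after quantile normalization. Arrays did not overlap for 50.9% of genes, against 10% by chance.

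OPT2, HXT4, DAL80, the ammonium permease MEP2, the stress sensor gene WSC4 and PUT1 were 27.4-fold, 21.6-fold, 20.1-fold, 19.9-fold, 16.9-fold and 16.2-fold higher. RGI2, SIP18, CYC1 and GRE1 were 24.1-fold, 18.6-fold, 13-fold and 11-fold lower. The tryptophan permease TAT2 was 9.59-fold lower (1 nitrogen-limited array at the floor), and the invertase gene SUC2, whose probe set shares probes with other sequences, 8.42-fold lower (log2 -3.07 ± 0.23 SE, adjusted p = 1.44e-07).

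Of 46 nitrogen catabolite repressed genes 30 were higher, 2 lower and 14 did not pass (32 and 2 adjusted over the list alone; camera adjusted p = 6.14e-19, adjusted p = 0.00241 with an estimated correlation). AGP1, at -1.17, was the largest exception. Of 17 Tir, Dan and Pau genes 11 were higher and 6 did not pass, with DAN4 at 1.69 (11 adjusted over the list alone; camera adjusted p = 0.000612, adjusted p = 0.361 with an estimated correlation). Of 17 phosphate starvation genes 9 were higher and 8 did not pass, with SPL2 at 1.90, lost with a floor of 50, and VTC1 at 1.16 (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00364, adjusted p = 0.329 with an estimated correlation). Of 42 autophagy genes 12 were higher, 2 lower and 28 did not pass, with YSP3 at 1.52 and ATG42 at 1.39 (14 and 2 adjusted over the list alone; camera adjusted p = 0.0265, adjusted p = 0.361 with an estimated correlation). Of 27 phospholipid synthesis genes 10 were higher, 2 lower and 15 did not pass, with INO1, inositol phosphate synthase, at 2.09 and CDS1 at -1.03 (11 and 2 adjusted over the list alone; camera adjusted p = 0.0267, adjusted p = 0.145 with an estimated correlation).

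Of 36 oxygen and heme responsive genes 26 were lower, 2 higher and 8 did not pass, with COX5A at -2.46 and AAC3 at 1.18 (28 and 3 adjusted over the list alone; camera adjusted p = 1.37e-11, adjusted p = 0.138 with an estimated correlation). Of 139 ribosome biogenesis genes 45 were lower, 1 higher and 93 did not pass, with NSR1 at -2.17, RCL1 at -1.81 and BUD23 at 1.10 (53 and 1 adjusted over the list alone; camera adjusted p = 1.11e-09, adjusted p = 0.329 with an estimated correlation). Of 35 glucose-repressed genes 17 were lower, 2 higher and 16 did not pass, with the maltose transporter MAL31, whose probe set shares probes with other sequences, at -2.34 and MLS1 at 3.25 (20 and 2 adjusted over the list alone; camera adjusted p = 8.66e-07, adjusted p = 0.138 with an estimated correlation). Of 81 ribosomal protein genes 21 were lower, 1 higher and 59 did not pass, with RPL9A at -2.16 and RPS1B, another with shared probes, at -1.41 (29 and 1 adjusted over the list alone; camera adjusted p = 3.14e-06, adjusted p = 0.415 with an estimated correlation). Of 21 TCA cycle genes 8 were lower and 13 did not pass, with PYC1 at -1.33 (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00307, adjusted p = 0.329 with an estimated correlation). Of 55 tRNA synthetases and translation factors 9 were lower and 46 did not pass, with CAM1 at -1.10 (8 adjusted over the list alone; camera adjusted p = 0.00663, adjusted p = 0.329 with an estimated correlation). Of 30 RNA polymerase I and III genes 4 were lower, 1 higher and 25 did not pass, with RPA49 at -1.51 and RRN6 at 1.04, lost with a floor of 50 (4 and 1 adjusted over the list alone; camera adjusted p = 0.0422, adjusted p = 0.361 with an estimated correlation). Control probe sets of ribosomal RNA read 149 ± 129 under nitrogen and 346 ± 96.5 under carbon limitation at 30 °C (SD, n = 3). With their level as a covariate, added after the data were seen, 825 genes differed and the call of CAM1 was lost. Since the level differed with the limitation, the covariate can also take up part of the limitation difference.

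At 12 °C, HXT2, SUC2, SUL1 and the maltose transporters MAL31 and MAL11 were lower and the pyruvate decarboxylase gene PDC5, HXT3 and MEP2 higher in nitrogen-limited than in carbon-limited cultures. HXT2 was 15.9-fold lower (557.3 ± 160 to 35.0 ± 10.4, SD, n = 3) and SUC2 11.3-fold lower (752.5 ± 196 to 67.0 ± 20.4). PDC5 was 5.84-fold higher (129.8 ± 11.7 to 756.4 ± 47.0). In all, 306 genes differed, 98 higher and 208 lower, and 116 by at least 2-fold, 43 higher and 73 lower. Only HXT2, SUC2, MAL31 and PDC5 still passed when the 12 °C arrays were fitted alone. Arrays did not overlap for 21.1% of genes, against 10% by chance.

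SUL1, MAL31 and MAL11 were 6.22-fold, 5.23-fold and 4.50-fold lower, and the polyamine transporter TPO2, HXT3, MEP2 and OPT2 were 4.90-fold, 3.78-fold, 3.72-fold and 3.30-fold higher. The probe sets of MAL31 and TPO2 share probes with other sequences, and 2 of 3 carbon-limited arrays lay at the floor for OPT2. Of 46 nitrogen catabolite repressed genes 4 were higher and 42 did not pass, with MEP2 at 1.90 and MEP1 at 1.22 (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00583, adjusted p = 0.261 with an estimated correlation). Of 28 glycolysis genes 2 were higher (2 adjusted over the list alone; camera adjusted p = 0.0134, adjusted p = 0.283 with an estimated correlation). Of 20 a-cell mating genes 1 was higher (1 adjusted over the list alone; camera adjusted p = 0.00036, adjusted p = 0.257 with an estimated correlation). Of 15 alpha-cell and sporulation markers 1 was higher, MF(ALPHA)2 at 1.52 (2 adjusted over the list alone; camera adjusted p = 0.0134, adjusted p = 0.257 with an estimated correlation). Of 30 iron and zinc genes 1 was higher and 1 lower, ISU1 at 1.02 and ATX1 at -0.93 (the same adjusted over the list alone; camera adjusted p = 0.0134, adjusted p = 0.549 with an estimated correlation). Of 37 proteasome genes 1 was higher (1 adjusted over the list alone; camera adjusted p = 0.0475, adjusted p = 0.549 with an estimated correlation). Of 20 trehalose and glycogen genes 7 were lower, with GAC1 at -1.67 and GSY1 at -1.27 (10 adjusted over the list alone; camera adjusted p = 0.000751, adjusted p = 0.549 with an estimated correlation). Of 36 oxygen and heme responsive genes 6 were lower and 1 higher, with COX5A at -1.10 (11 and 1 adjusted over the list alone; camera adjusted p = 0.0189, adjusted p = 0.549 with an estimated correlation).

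Of the 1452 genes that separated the limitations at 30 °C, 1379 (95%) had a smaller difference at 12 °C, with a median ratio of 0.240. Of the 306 genes at 12 °C, 192 (62.7%) had a smaller difference at 30 °C, with a median ratio of 0.686. Genes chosen for a call at one temperature tend to differ less at the other, so these shares and ratios partly reflect the choice. Over all genes the SD of the limitation log2 changes was 0.672 at 30 °C and 0.427 at 12 °C. Of the 306 genes, 162 differed in the same direction at both temperatures, 48 higher and 114 lower, where independent lists would give 14.0 and 26.2. Here too the contrasts share one estimate of each gene's spread, so the independent counts may be too low. Ribosomal RNA controls read 115 ± 114 and 260 ± 75.4 under nitrogen and carbon limitation at 12 °C (SD, n = 3). With their level as the added covariate 52 genes differed, 23 higher and 29 lower, and with a floor of 50, 153 did. Here again the covariate can take up part of the limitation difference. In the full fit the 12 °C groups share the spread of the 30 °C arrays, which varied less between replicates. With only the 12 °C arrays in the fit 4 genes passed, HXT2, SUC2, MAL31 and PDC5. The calls of SUL1, MAL11, TPO2, HXT3, MEP2, MEP1, OPT2, MF(ALPHA)2, ISU1, ATX1, GAC1, GSY1 and COX5A were lost. Median scaling gave 136 higher and 156 lower genes and quantile normalization 121 and 167. Without carbon limitation replicates 2 or 3, 196 and 133 genes differed, and without nitrogen limitation replicate 2, 128.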

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

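Of the tests in this part, the position of single arrays on the axis between the limitations was chosen only after the result was seen. The temperature effect differed between carbon and nitrogen limitation, by a test of the difference itself, for 402 genes, 35 of which changed in opposite directions, and for 14 gene lists. With an estimated correlation only 1 of these list calls held, that of nitrogen catabolite repressed genes. On the log2 scale (nitrogen minus carbon), BAP3 differed by at least 5.02, GNP1 by 4.23, SIP18 by 3.93, GRE1 by 3.71, RGI2 by at most 3.32, SHH3 by 2.92, PCK1 by 2.90 and CYC1 by 2.71. The floor could account for the value of RGI2. In the other direction the differences were -5.70 for HXT2, -4.74 for GAP1, -4.67 for DAL5, -4.52 for PUT1, -4.27 for HXT4, -3.92 for DUR3, -3.86 for DAL80 and -3.74 for CPS1. A signal also appeared in probe sets that the comparisons of named genes did not use, because they had several genes or were not listed. Of 1427 such probe sets over the floor, 336 changed in the same direction under both limitations, 89 upward and 247 downward.

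Regrouping of arrays argues against chance for 1 of the gene counts, that of genes with differing effects. Of 100 drawn splits by temperature within each limitation, only the real one (1 of 100) gave as many shared genes, 815 against 0 in the highest other. A shared gene needs a call under both limitations, and no other split within either limitation called a gene. The regrouping therefore does not test whether more genes are shared than chance gives. Of 100 by limitation within each temperature, drawn after the mean difference between the limitations was taken off each gene, only the real one (1 of 100) gave as many genes with differing effects, 402 against 0. For the 14 lists with differing effects chance cannot be excluded, since 8 of 100 splits called as many and the highest other called 16. For comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. There the real split gave 1386 and 2063 genes for temperature under carbon and nitrogen limitation and 1452 and 306 between the limitations at 30 °C and 12 °C, each against 0 in the highest other (1 of 10 splits as large). The corresponding list counts were 7 (3 of 10 splits as large, highest other 10), 14 (3 of 10, highest other 15), 12 (1 of 10, highest other 11) and 8 (3 of 10, highest other 10). Splits in which no gene passed thus called up to 16 lists.

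The limitations were separated by 1452 genes at 30 °C and by 306 at 12 °C. Greater scatter between the 12 °C arrays is argued against as the whole cause. After subtraction of the error variance, the variance of the limitation changes at 12 °C was 0.232 of that at 30 °C (0.175 to 0.261 when each array was left out), where equal differences would give 1. A single misplaced or mixed nitrogen-limited array at 12 °C would stand apart from the others of its group. On an axis from the carbon-limited arrays at 30 °C (0) to the nitrogen-limited ones (1), these 3 arrays lay at 0.489, 0.496 and 0.451. The carbon-limited ones at 12 °C lay at 0.252, 0.214 and 0.241. This argues against such an array on this axis only, in a test chosen after the result was seen. Across all genes, replicate 3 of nitrogen limitation at 12 °C correlated at 0.972 with carbon-limited replicate 1 at 12 °C. With its own replicates 1 and 2 it reached 0.957 and 0.981. A candidate explanation, a nutrient state that differed less between the limitations at 12 °C, stays open, as does a difference in how all cultures of a group were run, because residual nutrients were not analysed here.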

How the results depend on the processing

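The rRNA covariate and the restriction to protein-coding genes were chosen only after the result was seen. Over 11 counts of genes or lists and 17 alternatives apart from leaving out arrays, 146 values lay within 1.5 times the reported one and 17 did not. An adjusted p under 0.01 with at least a 2-fold change left 514 genes for temperature under carbon limitation, 777 under nitrogen limitation, 247 shared, 161 with differing effects, and 497 and 55 between the limitations at 30 °C and 12 °C, by the stricter threshold itself. With the rRNA covariate 825 and 52 genes separated the limitations at 30 °C and 12 °C. The rRNA control level itself differed between the limitations, so the covariate can take up part of their difference. The lower counts therefore do not show their cause. At 12 °C a floor of 50 gave 153 genes and 4 lists, and the cause was not tested. Between the limitations, only the 12 °C arrays gave 4 genes in place of 306, and only the 30 °C arrays gave 2044 in place of 1452. The shared estimate pools 12 °C arrays (median SDs of 0.26 and 0.28) with 30 °C arrays (0.18 under both limitations). For a typical gene it thus lies below the spread at 12 °C and above that at 30 °C. Fewer arrays also enter these fits. With an estimated correlation 0, 1, 1, 1 and 0 lists were called (temperature under carbon and nitrogen limitation, differing effects, limitations at 30 °C and 12 °C). In the same order fry called 19, 18, 13, 18 and 7 lists and kept 7, 14, 10, 12 and 5 of the camera calls. For differing effects it lost ribosomal proteins, ribosome biogenesis, amino acid biosynthesis and the TCA cycle. At 12 °C it lost iron and zinc regulons, the proteasome and oxygen and heme responsive genes.

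Leaving out each array gave 921 (without replicate 1 at 30 °C) to 1261 genes for temperature under carbon limitation, 1624 to 2045 under nitrogen limitation, 574 to 927 shared and 246 to 480 with differing effects, with 246, 249, 261 and 248 without carbon-limited replicates 1 and 2 and nitrogen-limited replicates 1 and 2 at 30 °C. Between the limitations it gave 1015 to 1086 at 30 °C and 128 to 394 at 12 °C, with 196, 133 and 128 without carbon-limited replicates 2 and 3 and nitrogen-limited replicate 2; fewer arrays enter these fits. The lists numbered 7 to 9, 11 to 15, 13 to 17, 11 to 14 and 4 to 10 in the order above, 4 without carbon limitation at 12 °C replicate 1.

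With the replicate number as a block, 1304, 1982, 765, 344, 1375 and 252 genes and 8, 14, 14, 12 and 10 lists passed, in the orders above. Whether the numbers pair the arrays cannot be told from 3 pairs per comparison. Correlations of same-numbered deviations were -0.195 to 0.0331 and -0.135 to 0.184 for temperature under carbon and nitrogen limitation. For the limitations they were 0.0664 to 0.107 at 30 °C (each array closest to its own number, 3 of 3) and -0.0571 to 0.0225 at 12 °C. For 523 pairs of a gene and a comparison, taken by the rule for named genes and list members, 10801 values were computed. Of these, 9948 kept direction and side of the threshold, 853 lost the threshold without reversing, and 0 reversed. A change brought to 0 by the floor would count among the 853. All pairs had passed in the main fit, mostly with large changes, so few reversals follow from the choice. Signal over background limits the dim genes, and a floor of 50 ended calls of several of them. Genes singled out after their values were seen were not all followed in this way.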

Other observations

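The tests by RNA class, the carry-over test and the test of a pheromone response were chosen only after the result was seen, while the tests of host genes and of the alpha1 gene were set beforehand. Of 40 measured small nucleolar RNAs, which guide the modification and processing of ribosomal RNA, 17 rose and 4 fell at 12 °C under carbon limitation and 20 rose and 3 fell under nitrogen limitation, with median changes of 0.56 and 0.76 on the log2 scale. SNR70 rose by 1.89 and 2.45 and SNR41 by 1.82 and 2.62, and SNR4 fell by 1.89 and by 1.40. Over the 4 tests of RNA classes, the camera adjusted p was 0.000419 under carbon and 1.05e-08 under nitrogen limitation (adjusted p = 0.344 and 0.224 with an estimated correlation). Of 83 tRNA genes, whose probe sets mostly share probes, 41 fell and 5 rose under carbon and 46 fell and 15 rose under nitrogen limitation, with medians of -0.81 and -0.75 (camera adjusted p = 1.85e-12 and 0.000392, adjusted p = 0.224 and 0.344 with an estimated correlation). Of 4 ribosomal RNA genes 3 and 2 fell, among them RDN5-1, by 1.93 and by 2.15, and of 4 spliceosomal RNA genes 1 and 3 fell, among them SNR7-L (the probe sets of RDN5-1 and SNR7-L share probes with other sequences).

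More small nucleolar RNAs rising than falling is a pattern that the arrays, hybridised with polyA RNA, could show for technical reasons. More carry-over of RNA without a tail at 12 °C would also raise the rRNA and tRNA genes. Their median changes were no higher than -0.80 (87 genes). These values were known when the test was chosen, and a fall of those RNAs could hide carry-over, so the test does not decide. Signal from longer host genes is argued against: the 37 small nucleolar RNAs in no annotated protein-coding gene had median changes of at least 0.57. A longer tail or slower processing of these RNAs at 12 °C may contribute and was not tested.

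The alpha-factor genes rose at 12 °C in cultures of mating type a: MF(ALPHA)1 went from 314 ± 99.0 to 1408 ± 307 under carbon and from 252 ± 75.9 to 2232 ± 348 under nitrogen limitation (SD, n = 3), and MF(ALPHA)2, at the floor on all arrays at 30 °C, rose by at least 1.26 and 2.78 on the log2 scale. Alpha cells, or expression of alpha mating-type genes in a cells, were predicted to raise the alpha1 gene by at least 1 on the log2 scale. The upper 95% limit of its change was at most -0.49 in the probe set over the floor on all 12 arrays. That probe set had mean signals of 24.4 at 12 °C and 58.6 at 30 °C. What it reads in a cells was not tested, so its fall could hide a rise. The other alpha1 probe set never exceeded 4.9, under the floor. The test therefore does not decide, and alpha cells stay open, also at a share too small to raise the alpha1 signal. The alpha-specific genes STE3 and SAG1 had changes of 0.83 and 1.01 under nitrogen limitation (adjusted p = 0.0145 and 0.0178). Under carbon limitation their changes were 0.62 and 0.49 (adjusted p = 0.0739 and 0.264). A general pheromone response may also contribute, but the a-cell mating list had medians of 0.06 and 0.23 with upper quartiles of 0.671 and 1.19 under carbon and nitrogen limitation, which decides nothing. A pheromone response cannot be told apart from a direct effect of temperature on these genes, which was not tested.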
